A study of Homo sapiens with 4 samples.

How the data were processed

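The series held 4 libraries of the human ovarian carcinoma line ES-2, 2 of parental and 2 of prexasertib-resistant cells, grouped by their titles. Per the labels' protocols, libraries were prepared with a strand-specific Kapa mRNA kit and sequenced on an Illumina NovaSeq as paired-end reads of 50 bp. The deposited counts are whole numbers of reads per gene symbol in each library; per the submitters' processing notes they came from STAR 2.7.3a on hg19, within the VIPER pipeline named in the design text. The annotation and the strand setting of that counting are not given in the sources used here, so antisense and overlapping genes are uncertain. The authors also deposited a table of a DESeq2 1.22.1 comparison and one of a limma 3.38.3 comparison of resistant with parental cells, per the file headers and the submitters' processing notes. In these, log2 fold changes and their standard errors are the authors', as are the p-values and adjusted p-values, the test statistics (a score with no fixed range), the mean log2 level and the mean of normalized counts per gene (a signal that is never negative). Their settings are not given in the sources used here, and their values were only set beside the new fit.

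Counts were analysed with edgeR 4.0.16 in R 4.3.3. Of 20114 genes, 3829 had 0 counts in all libraries and 12949 passed filterByExpr. TMM factors ran from 0.993 to 1.01. Resistant and parental cells were compared with the quasi-likelihood F test with no block, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold; the estimated biological coefficient of variation was 0.118. A standard error is the fold change divided by the square root of the F statistic. CPM values used the TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists, each with at least 5 tested genes; camera with an estimated correlation and fry were alternatives. Each list's members were also adjusted over the list alone.

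The groups, the tests, the 32 gene lists, the 6 lists of markers of other cell types, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean CPM of at least 5 and no overlap between the groups' libraries. It also took up to 4 members of each described list with the smallest adjusted p, or the member with the smallest p where none passed, and the 5 genes of highest mean CPM. CHEK1, FAM122A, WEE1, CDC25A, PPP2R2A, PPP2CA, CCNE1, ABCB1, ABCG2 and SLFN11 were always reported. Genes that fell in a list with few falls, and any gene outside the rule, were named after their values were seen. A few genes that the rule takes are left out of the text, although they count in every total.

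Depth was 31651653 and 51837010 counts in the parental and 25239232 and 34657571 in the resistant libraries, so that 3 counts in a library stood for 0.0944, 0.0583, 0.119 and 0.086 CPM. Where a group had 0 counts, a fold was given as a lower bound against 3 counts over that group, 0.036 CPM for parental and 0.05 CPM for resistant cells. With 1 to 3 counts it was given as a ratio of depth-scaled counts with an exact 95% interval. These intervals and floors cover counting error only.

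The tests were run on simulated counts of the same 12949 genes with 200 planted changes in 10 draws. edgeR recovered 36.9% of 1.5-fold, 82.6% of 2-fold and 97.3% of 4-fold changes, and 9.53% of its calls were false, above the nominal 5%. With 10 planted and 90 unchanged lists, camera called 10 and 0, camera with an estimated correlation 0 and 0, and fry 10 and 1. Each simulated gene was drawn independently, so these lists had no correlation between their genes.

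Alternatives were DESeq2 size factors (RLE) and upper-quartile factors, no filter and a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, an FDR of 0.01 and glmTreat against 1.5-fold. A fit without the mitochondrially encoded genes was chosen after seeing the data, since their share of counts differed between the groups.

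Neighbouring genes were taken from the RefSeq gene order of GRCh38.p14, in which 98.9% of tested genes were placed by symbol or synonym. Since the counts were made on hg19, that order was used only to say which genes adjoin, and no coordinates are given. Windows and neighbours used the 10237 placed genes with a mean CPM of at least 5. GC content and length came from the longest GENCODE 29 transcript, matched for 96.9% of tested genes, and loess corrections used statsmodels 0.14.6.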

Results

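RNA was sequenced from ES-2, an established human ovarian carcinoma cell line, as 2 libraries of the parental cells and 2 libraries of a derivative that had been made resistant to prexasertib, an inhibitor of the checkpoint kinase CHK1. The resistant cells had been selected on rising drug concentrations. The series' design text says that they were then kept in medium without drug, whereas the treatment label of the same libraries says treated with prexasertib, so whether drug was present at harvest is open. Gene counts summed to 31651653 and 51837010 in parental replicates 1 and 2, and to 25239232 and 34657571 in resistant replicates 1 and 2. Replicates of a group differed by more than counting noise, with a chi-square of 60.6 per degree of freedom between the parental libraries and 18 between the resistant libraries. The single comparison set resistant against parental cells. It asked which transcripts differ in cells that had become resistant, in a series whose title concerns CHK1 inhibition, phosphorylation of FAM122A and replication stress. All levels are CPM, counts scaled to library size, with the SD over n = 2 libraries, and fold changes are log2 values of resistant over parental with their standard errors.

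The largest rises in the resistant cells were ranked among called genes with a mean CPM of at least 5. Of the top 10, 4 belong to MHC class II, the proteins that present antigen to helper T cells. CD74, the invariant chain that accompanies class II molecules, rose from 0.604 CPM ± 0.0525 (SD, n = 2) to 242 CPM ± 12.7, a log2 change of 8.62 ± 0.18 (edgeR adjusted p = 4.64e-08). HLA-DRA rose from 0.264 to 102 CPM, a log2 change of 8.64 ± 0.21 (edgeR adjusted p = 8.86e-08). HLA-DOA went from 0 counts in both parental libraries to 11.6 CPM, at least 321-fold higher against a floor of 3 counts over the parental group. HLA-DQB1, with 1 parental count against 828, was 1150-fold higher with a 95% counting interval of 206 to 45400. The other genes among the 10 that rose most were PASD1, the T-cell gene TESPA1, the cancer-testis antigen SSX1, the mechanically gated channel PIEZO2, ELMO1 and the amine oxidase MAOA. Their log2 changes ran from 6.50 ± 0.27 for MAOA to 7.50 ± 0.28 for TESPA1, and PASD1, with 1 parental count against 1264, was 1750-fold higher (95% counting interval 314 to 69300). Genes of the class II family resemble one another and can share reads, so the values of single HLA genes are uncertain.

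**Figure D1:**
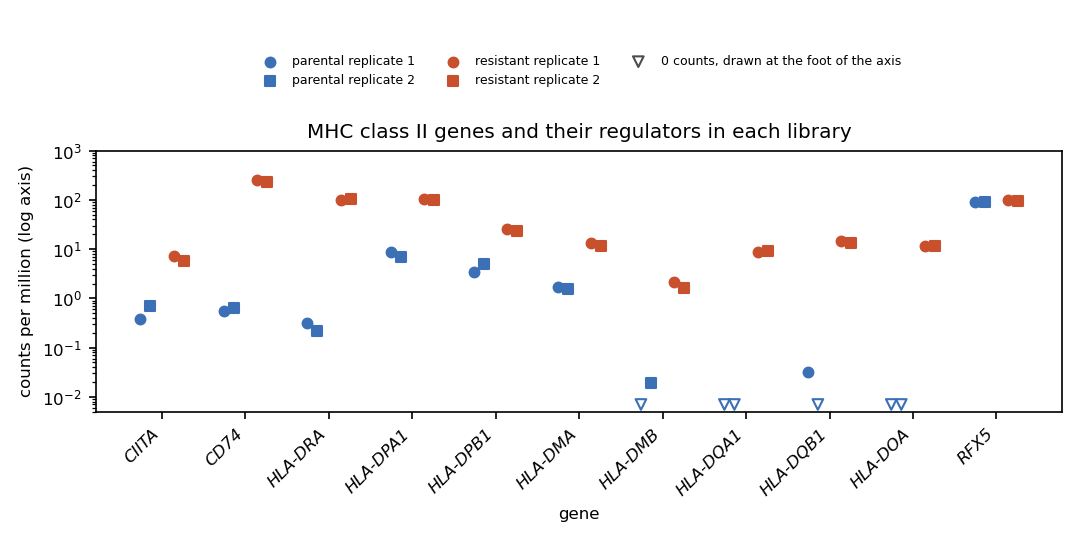
CPM on a log axis for MHC class II genes and regulators, with 1 symbol per library (circles replicate 1, squares replicate 2; open triangles at the foot of the axis are libraries with 0 counts). CD74 sits at 0.604 CPM on average in parental and 242 CPM in resistant cells, while RFX5 is at 90.2 and 98.3 CPM.

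Across the transcriptome, 5344 of 12949 tested genes passed an edgeR adjusted p of 0.05, with 2616 higher and 2728 lower in the resistant cells. Of these, 1933 changed by at least 2-fold, 1001 upward and 932 downward. The p-values measure only the spread between these samples, since the labels call the libraries duplicates and do not say that they came from separate cultures. The headers of both resistant count columns also carry the words P7 again, which the labels do not explain. The count of calls was 3007 without resistant replicate 1, 2889 without resistant replicate 2, 7416 without parental replicate 1 and 8028 without parental replicate 2. In simulated data of this design, with 200 changes planted among the 12949 genes, 9.53% of edgeR calls were false at the nominal 5%. Far fewer genes were changed there than were called here, so 9.53% need not be the false share among the 5344 calls.

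Interferon-stimulated genes rose as a group: 28 of 38 tested members rose, 1 fell and 9 did not pass, and adjusted over the list alone 30 rose and 2 fell. OAS2, which makes the activator of RNase L, rose from 0.802 to 9.20 CPM, a log2 change of 3.55 ± 0.25 (edgeR adjusted p = 1.38e-05). OAS3 rose by 3.04 ± 0.22, OAS1 by 3.55 ± 0.34 and XAF1 by 2.09 ± 0.20. The member that fell was IFIT5, at -0.80, chosen after its values were seen. The list passed camera at an adjusted p of 2.2e-08, but had an adjusted p = 0.738 with an estimated correlation. None of the 32 lists passed camera when the correlation was estimated. In the simulated data that setting called 0 of 10 lists planted with a change. A list that did not pass under it can therefore not be read as unchanged, here or below. With it, 1 of the 32 lists had an unadjusted p under 0.05, and 11 lists passed limma's fry.

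MHC class I and antigen processing genes, which load peptides for killer T cells, followed the same direction, with 17 of 19 members higher and PDIA3 alone lower, and 17 and 1 adjusted over the list alone. HLA-B rose from 138 CPM ± 33.6 to 508 CPM ± 42.0 (SD, n = 2), a log2 change of 1.88 ± 0.18 (edgeR adjusted p = 6.62e-05). HLA-F rose by 3.12 ± 0.23, and PSMB9, a subunit of the immunoproteasome, by 2.15 ± 0.17. The camera adjusted p was 1.98e-05, with an adjusted p = 0.738 with an estimated correlation.

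Among the 10 called genes with a mean CPM of at least 5 that fell most, 7 were zinc finger genes, a family of DNA-binding repressors. ZNF605 fell from 20.2 CPM ± 3.85 (SD, n = 2) to 0 counts in both resistant libraries, at least 390-fold lower against a floor of 3 counts over the group. ZNF585A likewise was at least 371-fold lower. TRIM58, a ubiquitin ligase gene, fell from 84.9 CPM to 1 count in the resistant pair against 7100 in the parental pair, a ratio of 5120 with a 95% counting interval of 918 to 202000. With 1 resistant count each, ZNF569 was 885-fold lower (95% counting interval 159 to 35000), ZNF717 822-fold (147 to 32500) and ZNF100 683-fold (122 to 27000), and ZNF680, with 2, was 310-fold lower (85.7 to 2570). ZNF254 had 599 and 716 counts in the parental libraries and 5 and 0 in resistant replicates 1 and 2, so its fold rests on 1 library. GPM6B, a neuronal membrane glycoprotein, was 215-fold lower (95% counting interval 73.4 to 1050), and FGF13 fell by 7.54 ± 0.23 on the log2 scale (edgeR adjusted p = 1.98e-07). Zinc finger genes share sequence, so reads can be split between them and their single values are uncertain.

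FAM122A, an inhibitor of the phosphatase PP2A and the protein named in the series title, fell from 20.5 CPM ± 1.30 (SD, n = 2) to 7.09 CPM ± 0.614, a log2 change of -1.53 ± 0.16 (edgeR adjusted p = 0.000138). CHEK1, the gene of the drug's target, rose from 23.7 to 42.2 CPM, by 0.84 ± 0.18 (edgeR adjusted p = 0.00547). WEE1, the kinase that restrains CDK1 and CDK2, rose by 1.00 ± 0.14 (edgeR adjusted p = 0.000584). The phosphatase gene CDC25A had a log2 change of -0.26 ± 0.15 (edgeR adjusted p = 0.2), the PP2A regulatory subunit PPP2R2A -0.15 ± 0.12 and the catalytic subunit PPP2CA -0.07 ± 0.12, none of which passed; CDC25A passed without parental replicate 2 (edgeR adjusted p = 0.0227, in a range over the alternatives up to 0.704). SLFN11, which blocks stalled replication forks, rose by 0.68 ± 0.13 (edgeR adjusted p = 0.00346), and the efflux transporter ABCG2 by 1.08 ± 0.17 (edgeR adjusted p = 0.00115). Cyclin E1, CCNE1, fell by 0.69 ± 0.22 (edgeR adjusted p = 0.0295) and the transporter ABCB1 fell by 0.79 ± 0.26 (edgeR adjusted p = 0.0352). Without resistant replicate 2 the adjusted p was 0.245 for CCNE1 and 0.234 for ABCB1, the highest of all alternatives, whose lowest were 0.00179 and 0.00084; both calls also ended without resistant replicate 1 and with DESeq2, and that of ABCB1 with limma-voom (adjusted p = 0.0509).

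FAM122A lies within the span of PIP5K1B on the same strand, and PIP5K1B had 0 counts in the parental and 9 in the resistant libraries, against 1722 and 421 for FAM122A. The genes next to FAM122A were lower as well: of the 10 tested genes with a mean CPM of at least 5 on either side in the GRCh38.p14 gene order, 18 fell and 0 rose. The 10 that follow FAM122A lay between -1.83 and -0.85 on the log2 scale, with C9orf85 the lowest at -1.83 ± 0.16, and the 10 that precede it between -1.18 and -0.12. C9orf85 and this comparison of neighbours were chosen after their values were seen.

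Of the 25 tested PP2A subunits and regulators, 4 rose and 2 fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.848). PPP2R2B rose from 0.955 to 5.81 CPM, a log2 change of 2.63 ± 0.26 (edgeR adjusted p = 9.7e-05), and IGBP1 by 1.04 ± 0.14. KIAA1524, which encodes the PP2A inhibitor CIP2A, had a log2 change of -0.81 ± 0.16. In the replication checkpoint list, 7 of 23 members rose and 6 fell, and 7 and 7 adjusted over the list alone (camera adjusted p = 0.77). CLSPN, the adaptor of CHK1, rose by 1.04 ± 0.21 and TIMELESS by 0.73 ± 0.13, while ATR, the kinase upstream of CHK1, fell by 0.81 ± 0.16 (edgeR adjusted p = 0.00382). Of 28 tested genes of CDK1/CDK2 and CDC25 control, 13 rose and 6 fell, and 15 and 6 adjusted over the list alone (camera adjusted p = 0.174). E2F1 rose by 1.00 ± 0.14 and CDK6 fell by 1.28 ± 0.15 (edgeR adjusted p = 0.000208). The CDK inhibitor CDKN1C, with 3 parental counts against 75, was 34.7-fold higher (95% counting interval 11.4 to 172).

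Genes of replication origin licensing and the fork rose in 25 of 42 cases, and 4 fell, with the same numbers adjusted over the list alone. PRIM1, a primase subunit, rose from 14.5 CPM ± 2.26 to 43.0 CPM ± 0.422 (SD, n = 2), a log2 change of 1.58 ± 0.15 (edgeR adjusted p = 7.41e-05). CDT1 rose by 1.35 ± 0.14, the histone chaperone ASF1B by 1.41 ± 0.15 and POLA1 by 1.23 ± 0.15, whereas ORC2, ORC6, RFC3 and DBF4 fell. By limma's fry the whole list did not pass (fry adjusted p = 0.105). The list passed camera at an adjusted p of 0.00055, but had an adjusted p = 0.908 with an estimated correlation, and 13 members rose without resistant replicate 2. Mitotic genes rose in 19 of 39 cases and 4 fell, AURKA, BUB1B, MAD2L1 and CENPF, with the same numbers adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.738 with an estimated correlation). INCENP rose by 1.14 ± 0.14, CDCA5 by 1.04 ± 0.13 and KIF20A by 1.02 ± 0.14. The mitotic list's camera adjusted p was 0.0544 without parental replicate 2, and 11 members rose without resistant replicate 1.

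In nucleotide synthesis, 7 of 25 genes rose and 5 fell, and 7 and 6 adjusted over the list alone (camera adjusted p = 0.66). TYMS, thymidylate synthase, rose from 58.1 CPM ± 19.7 to 225 CPM ± 12.3 (SD, n = 2), a log2 change of 1.96 ± 0.21 (edgeR adjusted p = 0.000135). Among 39 homologous recombination and fork protection genes, 9 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.622). That list passed without parental replicate 1 (mean log2 change 0.30, camera adjusted p = 0.039, in a range over the alternatives up to 0.957) and had a mean of -0.05 without parental replicate 2. FANCE rose by 1.11 ± 0.17, and the helicase gene WRN fell by 0.88 ± 0.14. None of the 6 tested replication-dependent histone genes passed edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.622), and HIST2H2BE had the smallest p, with a log2 change of -0.68 ± 0.25 (edgeR adjusted p = 0.0553). HIST2H2BE passed without either parental replicate, with the replicate block and with no filter, in a range of adjusted p from 0.000375 to 0.466. Histone genes are near-copies of one another and their values are uncertain.

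The list of ABC drug efflux transporters, which also holds a vault protein gene, was mixed. Of its 14 tested members 2 rose and 3 fell, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.656). MVP, the major vault protein, rose by 1.10 ± 0.13, and ABCA1, the cholesterol exporter, fell by 1.58 ± 0.15 (edgeR adjusted p = 6.83e-05). Of 27 apoptosis regulators, 8 rose and 7 fell, and 8 and 8 adjusted over the list alone (camera adjusted p = 0.852). The antiapoptotic BCL2A1 fell from 62.9 CPM ± 1.07 to 6.24 CPM ± 0.947 (SD, n = 2), a log2 change of -3.32 ± 0.16 (edgeR adjusted p = 2.02e-06), and MCL1 fell by 1.08 ± 0.14. Of 28 p53 target genes, 5 rose and 7 fell, and 6 and 10 adjusted over the list alone (camera adjusted p = 0.694). EDA2R rose by 3.70 ± 0.19 and AEN fell by 1.29 ± 0.14.

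Inflammatory genes split: of 27 NF-kB cytokines and chemokines, 9 rose and 12 fell, and 9 and 13 adjusted over the list alone (camera adjusted p = 0.28). PTGS2, cyclooxygenase-2, fell from 40.9 to 1.68 CPM, a log2 change of -4.61 ± 0.23 (edgeR adjusted p = 2.43e-06), and CXCL5 fell by 1.60 ± 0.16, while IL24 rose by 2.58 ± 0.14. Of 24 genes of MAPK pathway output, 3 rose and 12 fell, and 3 and 13 adjusted over the list alone (camera adjusted p = 0.0925). SPRY4, a feedback inhibitor of the pathway, fell by 1.31 ± 0.12, and the cyclin gene CCND1 rose by 0.98 ± 0.14. Of 19 TGF-beta targets, 4 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.374), and of 22 YAP/TAZ targets, 8 rose and 3 fell, again the same (camera adjusted p = 0.77). CTGF, a member of both, fell from 1588 CPM ± 104 to 294 CPM ± 26.8 (SD, n = 2), a log2 change of -2.43 ± 0.15 (edgeR adjusted p = 6.03e-06).

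Wnt pathway genes rose in 10 of 17 cases, and LEF1 and LGR5 fell; adjusted over the list alone, 11 rose and 2 fell. WNT5A, a noncanonical Wnt ligand, rose from 1.38 CPM ± 0.352 to 80.3 CPM ± 2.57 (SD, n = 2), a log2 change of 5.82 ± 0.19 (edgeR adjusted p = 3.55e-07). WNT5B rose by 1.58 ± 0.14 and AXIN2, a feedback inhibitor, by 2.01 ± 0.23, and RNF43 was 88.8-fold higher (95% counting interval 24.1 to 741, from 2 parental counts). The camera adjusted p was 0.00312, with an adjusted p = 0.738 with an estimated correlation, and 0.0832 over genes with a mean CPM of at least 5. Of 33 receptor tyrosine kinases and ligands, 13 rose and 7 fell, and 13 and 8 adjusted over the list alone (camera adjusted p = 0.473). KIT rose from 4.10 to 44.7 CPM, by 3.47 ± 0.20 (edgeR adjusted p = 4.86e-06), and ERBB2 by 3.57 ± 0.21, while FGF2 fell by 1.56 ± 0.12.

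Of 26 epithelial genes 13 were tested, of which 8 rose and 0 fell, the same adjusted over the list alone. Among those that rose, CLDN4, CLDN7 and DSP reached only 0.786, 0.993 and 0.394 CPM in resistant cells. The keratins KRT7 and KRT8 rose by 1.10 ± 0.18 and 0.98 ± 0.14, and the desmosomal gene PKP3 by 1.69 ± 0.22 (edgeR adjusted p = 0.000446). The camera adjusted p was 0.0122, with an adjusted p = 0.738 with an estimated correlation, and 0.0832 over genes with a mean CPM of at least 5. Of 29 mesenchymal genes, 14 rose and 4 fell, and 14 and 5 adjusted over the list alone (camera adjusted p = 0.0738); over genes with a mean CPM of at least 5 that list passed camera (adjusted p = 0.0163), as it did fry, in a range over the alternatives up to 0.846. THY1 rose from 15.4 CPM ± 0.119 to 111 CPM ± 6.90 (SD, n = 2), by 2.84 ± 0.13 (edgeR adjusted p = 1.77e-06), PDGFRB by 2.35 ± 0.21 and SPARC by 1.60 ± 0.13. Of 39 genes of collagens and matrix, 17 rose and 11 fell, and 17 and 12 adjusted over the list alone (camera adjusted p = 0.551). COL5A1 rose by 1.72 ± 0.12 and the laminin gene LAMA1 fell by 5.53 ± 0.28 (edgeR adjusted p = 2.6e-06).

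**Figure D2:**
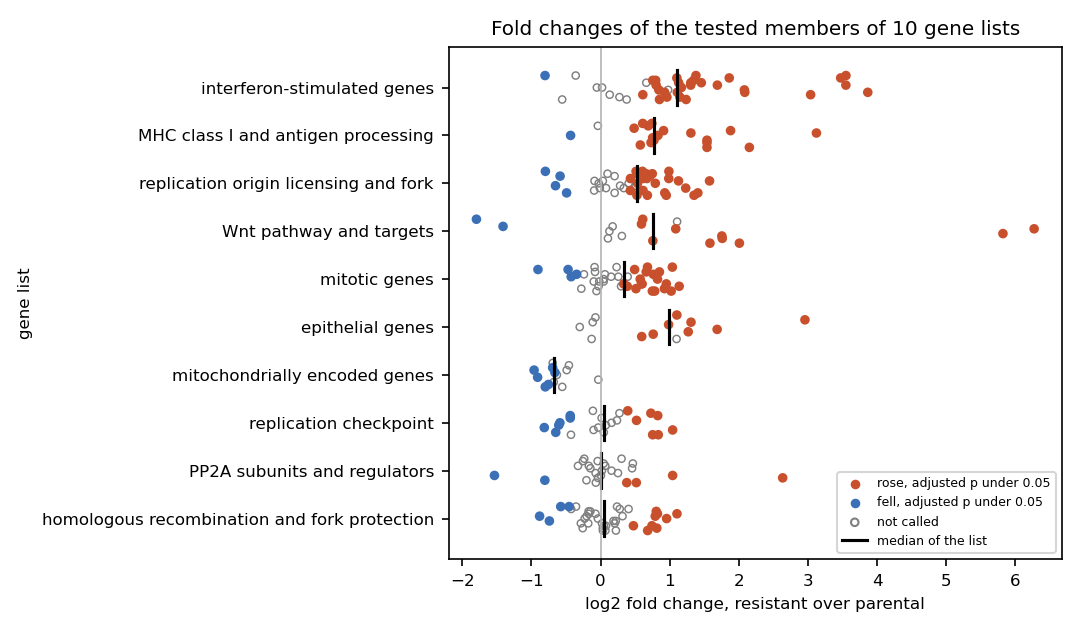
Log2 fold changes of resistant over parental cells for each tested member of 10 gene lists, filled where the edgeR adjusted p was under 0.05, with a black bar at each list's median. The medians lie at 1.11 for interferon-stimulated genes, 0.77 for MHC class I genes and 0.01 for PP2A subunits and regulators.

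Lineage genes changed in part. Of 34 HOX genes, 1 rose and 6 fell, and 1 and 4 adjusted over the list alone (camera adjusted p = 0.473). The HOX list passed without parental replicate 1 (mean log2 change -0.42, camera adjusted p = 0.039, in a range over the alternatives up to 0.957) and had a mean of 0.01 without parental replicate 2. HOXC10 rose by 0.99 ± 0.21 and HOXA11 fell by 1.93 ± 0.29. Of 8 ovarian and clear cell carcinoma markers, 4 rose and WT1 fell, the same adjusted over the list alone (camera adjusted p = 0.174), and ESR1, the estrogen receptor, rose from 0.663 to 6.38 CPM (edgeR adjusted p = 2.21e-05). Of 14 cancer-testis antigens, 6 rose and 5 fell, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.433). MAGEA1 rose by 4.02 ± 0.29 while MAGEA10 fell by 6.70 ± 0.36, in a family whose members can share reads.

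Mitochondrially encoded transcripts fell in 6 of 13 cases and 0 rose, and 8 fell adjusted over the list alone. MT-CYB fell from 2692 CPM ± 303 to 1383 CPM ± 481 (SD, n = 2), a log2 change of -0.96 ± 0.23 (edgeR adjusted p = 0.00919), a call that ended without resistant replicate 2 (edgeR adjusted p = 0.0971, in a range over the alternatives from 4.7e-10). These genes held 4.8% and 4.09% of parental counts and 3.4% and 2.12% of resistant counts. As a list they did not pass limma's fry (fry adjusted p = 0.429). The camera adjusted p was 0.0216, with an adjusted p = 0.957 with an estimated correlation, and 0.193 without resistant replicate 2, where 0 members fell; it was also over the threshold without parental replicate 1 (0.0936) and replicate 2 (0.126). Nuclear-encoded oxidative phosphorylation genes rose in 3 of 41 cases and fell in 8, the same adjusted over the list alone (camera adjusted p = 0.656), with NDUFA4 at -0.68 ± 0.15, a call that ended without resistant replicate 1 (edgeR adjusted p = 0.136, in a range from 1.32e-08). Of the 50 ribosomal protein genes, 1 rose and 4 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.855). The transcripts of highest mean level were EEF1A1, MMP1, MT-CO1, MT-ND4 and EEF2, of which MMP1, a collagenase at 9859 CPM in parental and 5651 CPM in resistant cells, passed edgeR (log2 change -0.80 ± 0.18, edgeR adjusted p = 0.00621). The MMP1 call ended without resistant replicate 1 (edgeR adjusted p = 0.103, in a range over the alternatives from 3.21e-07). MT-CO1 and MT-ND4 did not pass edgeR but were lower past the threshold in 8 of 12 alternatives each, with an adjusted p from 3.38e-06 to 0.465 and from 1.01e-05 to 0.498. EEF2 passed as higher without parental replicate 2 (edgeR adjusted p = 0.00486, in a range up to 0.468) and with limma-voom and the block.

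In glycolysis and hypoxia, 7 of 28 genes rose and 2 fell, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.374). NDRG1 rose by 1.97 ± 0.27, and the carbonic anhydrase CA12 went from 618 counts to 1, a ratio of 446 with a 95% counting interval of 79.7 to 17600. In cholesterol synthesis, 10 of 25 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.174), and CYP51A1 fell by 1.10 ± 0.16. The cholesterol list passed without parental replicate 1 (mean log2 change 0.44, camera adjusted p = 0.034) and not without parental replicate 2 (0.19, camera adjusted p = 0.464), in a range over the alternatives up to 0.957. Among 22 NRF2 targets, 3 rose and 3 fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.848), with GCLM at -1.73 ± 0.14. Among 27 genes of the unfolded protein and ATF4 response, 3 rose and 3 fell, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.898), with the serine synthesis gene PSAT1 at -1.74 ± 0.14. The p53 list had a median log2 change of -0.15 and a mean of 0.04, the YAP/TAZ and NRF2 lists had medians of -0.03 and -0.01 with a camera direction upward, and the unfolded protein list had a median of 0.01 and a mean of -0.04.

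Markers of other cell types gave no rise of a whole list. Of 13 blood cell markers, only CD68 and CORO1A were tested, 0 passed, and CD68 was at 106 CPM in parental and 112 CPM in resistant cells. Of 9 endothelial markers, 5 were tested, 1 rose (CDH5) and 3 fell (KDR, ESAM and EGFL7). Of 8 squamous markers 1 was tested, TP63, and it did not pass. Of 10 neuronal markers 5 were tested, TUBB3 rose and SYP fell. Of 7 melanocytic markers 3 were tested and DCT fell, and of 7 hepatic markers 1 was tested, SERPINA1, which rose from 27.2 to 44.4 CPM.

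The authors' deposited DESeq2 table called 5097 of 16285 genes, 2518 higher and 2579 lower in resistant cells, and 92.4% of the edgeR calls were among them in the same direction. The authors' deposited limma table called 6390 of 20114 genes, 3281 higher and 3109 lower, and held 99.9% of the edgeR calls. In the authors' deposited tables FAM122A had log2 changes of -1.54 by DESeq2 and -1.54 by limma. No gene called by edgeR and either table had opposite directions. In the limma table, the 3829 genes with 0 counts in all libraries had a median log2 change of 0.45, beside a depth ratio of parental to resistant libraries of 0.45 on the log2 scale, and 0 of them were called. That table called 554 of the 7165 genes outside the tested set, 367 higher and 187 lower.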

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

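Of the tests in this part, only the fit without mitochondrially encoded genes was chosen after seeing the data. The count of genes past an edgeR adjusted p of 0.05 was 5344 and lay between 4042 and 6268 under RLE or upper-quartile factors, no filter, a mean CPM of at least 5, DESeq2, limma-voom and the replicate block; it was 3273 at an FDR of 0.01. Leaving out each library in turn gave 2889 to 8028 calls, with the lone library of a group assumed to vary like the other group's pair. Those counts fell without a resistant replicate and rose without a parental replicate, which leaves the more alike resistant pair as the only measure of spread. Without the mitochondrially encoded genes 5337 genes passed. Genes that also changed 2-fold numbered 1933 and ran from 1716 to 2296 with each library left out, but 899 at a mean CPM of at least 5, where fewer genes were tested. With edgeR and the replicate block, 6268 genes passed; same-numbered libraries deviated with a correlation of 0.143 across genes, and as the labels tie the numbers to no shared culture or day, the libraries share only a number. The block changed the call of 0 gene lists. Camera called 7 lists, 6 over genes with a mean CPM of at least 5 and 0 with an estimated correlation. Fry called 11, of which 5 were among the 7. In the simulated data camera with an estimated correlation called 0 of 10 planted lists, where camera and fry called 10 each. Its 0 here therefore cannot show that the lists are unchanged. The simulated genes were drawn independently, so the simulation does not show how camera with its preset correlation of 0.01 behaves on correlated lists. Among the 7 lists called here, the estimated correlation ran from -0.0342 for epithelial genes to 0.814 for mitochondrially encoded genes. The cause of the other differences was not tested. The ribosomal protein list, with a mean log2 change of 0.02, turned to -0.195 without parental replicate 1 (camera adjusted p = 0.039) and stood at 0.234 without parental replicate 2 (camera adjusted p = 0.0458); the cause was not tested. The authors' deposited DESeq2 table shared 92.4% of the edgeR calls and the one from limma 99.9%. All 152 named genes kept their direction and side of the threshold with RLE and upper-quartile factors; 13 lost the call without resistant replicate 1 and 16 without resistant replicate 2. Depth limits single values under about 0.119 CPM, the level of 3 counts in the shallowest library.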

Other observations

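The tests of this part were chosen after the results they address were seen, except that the outcome of the GC and length correction was predicted before it was computed. Beyond the genes described so far, further MHC class II genes and their activator were higher in resistant cells. CIITA, the activator, rose from 0.538 CPM ± 0.227 to 6.54 CPM ± 0.985 (SD, n = 2), a log2 change of 3.53 ± 0.31 (edgeR adjusted p = 4.6e-05). HLA-DPA1 rose by 3.70 ± 0.15, HLA-DMA by 2.94 ± 0.21 and HLA-DRB1 by 6.35 ± 0.18, and HLA-DQA1 went from 0 counts to 8.96 CPM, at least 249-fold higher. Of the constitutive factors, RFX5 did not pass, at 0.12 ± 0.12 (edgeR adjusted p = 0.421), RFXAP fell by 0.69 ± 0.18 (edgeR adjusted p = 0.0142), NFYB rose by 0.73 ± 0.14 (edgeR adjusted p = 0.003), and RFXANK, NFYA and NFYC did not pass. The interferon feedback gene SOCS1 rose by 3.90 ± 0.55 and IRF1, a transcription factor of the interferon response, by 1.35 ± 0.13, while JAK2, a kinase of interferon receptors, fell by 0.63 ± 0.15 (edgeR adjusted p = 0.00989) and IFNGR1 (0.02 ± 0.13) and JAK1 (0.30 ± 0.12) did not pass.

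Protocadherin beta genes, adhesion genes that lie in 1 cluster, fell together. All 12 tested members fell by at least 3 on the log2 scale with edgeR, and passed as lower with RLE and upper-quartile factors too. Their levels summed to 24.2 CPM in parental and 0.374 CPM in resistant cells. The protocadherin gamma genes did not share this fall, since of 13 tested, 2 rose and 3 fell. Zinc finger genes with a ZNF symbol made up 60 of the 242 genes that fell that far, 24.8% against 3.39% of the 12548 genes expressed highly enough for such a fall. The protocadherin beta and ZNF families were singled out after these falls were seen. A Fisher's exact test that was run on the same falls restates that choice, and its p is not given. Of 430 tested ZNF genes, 162 fell and 35 rose, the same with RLE factors, and 157 and 39 with upper-quartile factors.

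Genes that adjoin in the GRCh38.p14 order moved together elsewhere too. Medians over 21 successive genes with a mean CPM of at least 5 were set against a limit of 0.599 in size. Of 200 shuffles of the gene order, 95% stayed under that limit. The medians passed it in 40 runs, 21 lower and 19 higher in resistant cells. Some runs share genes, and merging those left 32 stretches. Stretches counted apart can still lie near one another, and how they spread over the chromosomes was not examined. The runs held 10.6% of the ordered genes and 18.9% of the calls among them. The lowest run, 52 genes from RECK to ISCA1 with a median log2 change of -0.89, held FAM122A, and 39 of its genes fell and 0 rose.

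FAM122A fell together with genes next to it in the gene order, which does not give distances. The 20 nearest in that order, among tested genes with a mean CPM of at least 5, had a median log2 change of -1.17. The median was -1.43 for the 10 that follow and -0.89 for the 10 that precede. The median of all 20 lay outside the -0.275 to 0.274 that held 95% of 10000 random lists matched on expression. That argues against a change of FAM122A alone. After correction for GC content and transcript length the median was -1.06, still outside the -0.262 to 0.249 of random lists, against those biases as the whole cause. Loss of DNA copies over the region is a candidate explanation that stays open: the neighbours' median absolute deviation was 0.27, and 24.0% of random lists had one as small, which neither shows nor excludes a common shift. Regional regulation, and any part that resistance has in it, was not tested.

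The 60 ZNF genes that fell by at least 3 on the log2 scale, several of them to 0 or 1 count, lost 305 CPM in sum. Had those reads moved to other family members, the other ZNF genes together were to gain at least 50% of that loss. They changed by -414.0% of it. That sum also holds ZNF genes that fell by less, so it could hide a gain by close relatives. Reads shared between family members thus stay open. Deletion of whole clusters cannot be told apart from the loss of single genes: of 15 tested genes between lost members, at most 3 places away, the 12 with a ZNF symbol could not show such a fall, by the way members were picked. The other 3, ZFP30 (0 resistant counts), HKR1 and RPSAP58, had a median log2 change of -1.19 and are too few to decide, in the third form that this test was given after values were seen. Silencing by chromatin was not tested.

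The rise of MHC class II genes does not go with blood cells in the culture, since the 12 blood cell markers other than CD68 summed to 0.783 CPM in resistant cells, beside 242 CPM of CD74. Reads shared between HLA genes cannot give the rise of CD74, at 8.622 on the log2 scale, or of CIITA. Another cell line in place of the resistant cells could not be excluded: 20.6% of the tested HOX genes were called, fewer than the 41.3% of all tested genes, and between the limits of 50% set for a different line and 5% set against one, as were the 8.82% without resistant replicate 2 and the 48.5% without parental replicate 2, the lowest and highest with a library left out. The 5% limit stood for what passes by chance, while 41.3% of all tested genes were called. It could hardly be met, so the HOX share does not decide the question. TIE1, at 202 and 235 CPM, and TP63, at 80.8 and 66.3 CPM, were abundant in both groups. A response to interferon in the resistant cells may also account for the rise and was not tested further.

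HLA-DOA at 0 parental counts limits the resistant profile in the parental libraries to 0.311%, and ZNF605 at 0 resistant counts limits the parental profile in the resistant libraries to 0.256%, for counting error only.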
